A study of Canis lupus familiaris with 15 samples.

How the data were processed

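RNA was measured from Madin-Darby canine kidney (MDCK) cells, an established line of dog kidney epithelium that forms a polarised layer on a porous filter. Total RNA was labelled with biotin and hybridised to 15 Affymetrix canine arrays, 1 per culture sample. Per the labels, cells were kept on Transwell filters for 7 days and fell into 4 groups. These were medium alone (Control, n = 4), hepatocyte growth factor at 100 ng/ml for 24 h (HGF, n = 4), HGF with a compound spelled PD09859 at 50 uM (HGF + PD, n = 4), and HGF with a compound spelled UO126 at 10 uM (HGF + UO, n = 3). The series title calls the compounds MAPK inhibitors, and the names were read as the MEK inhibitors PD98059 and U0126, which block the kinase upstream of ERK. No arrays of cells given a compound without HGF were analysed, and a vehicle control is not given in the sources used here.

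The deposited values are linear probe intensities that the authors summarised per probe set with GCRMA, per the submitters' processing notes. GCRMA subtracts an estimated background that depends on probe sequence, normalises between arrays and combines the probes of a set. Its version is not given in the sources used here, nor is the annotation behind the summary. The table held 43035 probe sets with intensities from 1.97 to 104385. GCRMA compresses dim probe sets towards a floor, so that a large fold change of a gene near the floor in 1 group depends on the background estimate. Depth in the sense of read counts does not apply to arrays, and the number of arrays limits the precision.

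Log2 was taken of the deposited intensities, with no further scaling. The 111 control probe sets of the array maker were left out of all tests and used for array checks. Probe sets with a log2 intensity of at least 4 on at least 3 of the 15 arrays were kept, which left 24904 (58.0% of those that are not controls). Gene names came from the platform annotation, which lists 29254 probe sets with 1 symbol, 439 with several and leaves 13231 unlisted. Probe sets with several symbols were not named, and 0 symbols changed when updated through the Entrez identifier. Of the probe sets kept, 18490 had 1 symbol. Each gene was represented by its probe set with the highest mean over all arrays, giving 10286 genes.

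Differences were tested with limma 3.58.1 in R 4.3.3. A linear model (lmFit) with 1 mean for each of the 4 groups was fitted to all 15 arrays, and eBayes was run with a variance trend. Benjamini-Hochberg adjustment ran over the probe sets kept, with a threshold of 0.05. All groups share 1 estimate of the spread because each has few arrays. Changes are given as log2 differences ± the standard error (SE) of the fit. Every adjusted p-value of a single gene comes from this fit. The labels call the arrays biological replicates, without saying whether cultures were grown at separate times, so the p-values measure the spread between these arrays.

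A total of 28 gene lists with 555 genes was fixed before the data were examined, of which 491 genes had an annotated probe set and 392 were measured. Lists were tested with camera (limma), which compares a list with the other genes, at a preset correlation between genes of 0.01 and again with the correlation estimated from the residuals. Adjustment ran over the 28 lists within a comparison. Counts of changed members use the adjustment over all probe sets unless given as adjusted over the list alone. The mean change of each list was also set against 10000 random lists matched on the HGF change, which does not allow for correlation between members.

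The rule for named genes was also fixed before the data were examined. It took the 10 largest changes each way among genes past the threshold whose arrays did not overlap (5 each way between the inhibitors), the 3 members with the lowest adjusted p of each list past the threshold, and 11 genes set in advance. Of those 11, SPRY2, PLAUR and CYP1A1 had no usable probe set and are not reported. The largest changes opposed under both inhibitors were added by the same rule, 10 each way. Other genes given below as examples of a list were chosen from its members after their values were seen.

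A probe set was counted as opposed when it passed the threshold for HGF against Control and, in the other direction, for inhibitor against HGF. Both comparisons use the same HGF arrays. The counts were therefore set beside simulations of unchanged groups (20 for calls, 100 for correlations), beside the overlap of independent sets of calls, and beside values from the 6 splits of the HGF arrays into pairs. In these splits 1 pair chose the probe sets and gave the HGF change, and the other pair gave the change under the inhibitor. No arrays were near-identical. Array measures were compared with two-sided exact permutation tests.

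The procedure was tested on simulated data with the spread of these arrays. Only 50 of the 24904 probe sets were changed at each size. For HGF against Control, 96% of changes of 1 on the log2 scale, 72% of changes of 0.5 and 12% of changes of 0.25 were recovered. For UO against PD the shares were 98%, 76% and 8%. With so few changes the adjusted threshold is stricter than in the real comparisons, where 13839 and 2295 probe sets passed. The shares therefore do not tell how many changes the real comparisons missed. A simulated opposed share of 70% was estimated as 69.3%, and 1 of 90% as 89.2%.

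Alternatives fixed before the data were examined were no filter, a filter at log2 6, quantile and cyclic loess normalisation of the log2 values, no variance trend, a fit of only the groups compared, the replicate number as a block, array weights, a required change of 1 on the log2 scale, the mean of all probe sets of a gene for the lists, other probe sets of each named gene, and leaving out each array in turn.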

Results

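Gene expression was profiled in MDCK cells grown on filters and left in medium, given hepatocyte growth factor (HGF) for 24 h, or given HGF together with 1 of 2 MAPK pathway inhibitors. HGF is the ligand of the receptor tyrosine kinase MET and scatters MDCK colonies. The series was designed to find the genes that HGF regulates through the MAPK pathway. The HGF + PD group received 50 uM and the HGF + UO group 10 uM, so the inhibitors were not compared at matched doses. The median intensity was 41.4 ± 0.362 (SD, n = 4) on the Control arrays, 40.6 ± 0.206 (n = 4) on HGF, 40.7 ± 0.302 (n = 4) on HGF + PD and 41.5 ± 0.918 (n = 3) on HGF + UO. Between 56.9% and 57.8% of probe sets reached the filter level on each array. The first principal component held 71.2% of the variance and set the 4 HGF arrays (87.8 to 94.3) apart from the other 11. The second held 15.2% and separated the Control arrays from both inhibitor groups.

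**Figure D1:**
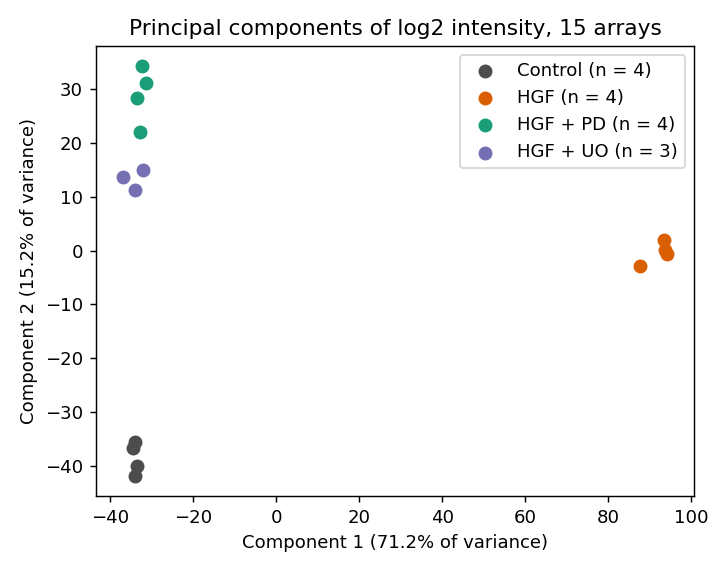
First and second principal components of log2 intensity (arbitrary units), each point 1 array coloured by group (Control, HGF and HGF + PD n = 4, HGF + UO n = 3). The HGF arrays lie at 87.8 to 94.3 on component 1, which holds 71.2% of the variance, and the arrays of the other groups lie below 0.

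The widest rises with HGF included genes of matrix breakdown and of its inhibition. MMP13, a collagenase, rose from a log2 intensity of 4.27 ± 0.18 to 11.85 ± 0.49 (SD, n = 4 and 4), a change of 7.58 ± 0.20 or 192-fold (adjusted p = 9.34e-13). Its Control level lay near the filter level of 4, so the size of this change depends on the GCRMA background. TIMP1, an inhibitor of matrix metalloproteinases, rose by 7.41 ± 0.09 (170.2-fold, adjusted p = 3.31e-16). SNAI2, a transcriptional repressor of epithelial genes, rose by 5.82 ± 0.18 and PTGS2, the inducible cyclooxygenase, by 6.33 ± 0.21. SERPINE2, a serine protease inhibitor, rose by 5.74 ± 0.11 and the calcium-binding S100A2 by 6.34 ± 0.07. DSG3, TFPI2, FGFBP1 and ISG20 rose by 7.57 ± 0.06, 7.18 ± 0.14, 6.29 ± 0.29 and 6.09 ± 0.11, each from a Control level below the filter, so that the size depends on the GCRMA background. The deepest fall was that of PDZK1, a scaffold for transporters of the apical membrane (-7.03 ± 0.35, 130.5-fold). Changes were -5.02 ± 0.13 for NTN4, a laminin-related matrix protein, -5.19 ± 0.26 for SCG5, a secretory granule chaperone, and -4.80 ± 0.35 for CLDN2, the pore-forming claudin of leaky epithelia. CLTRN and TEX26 changed by -6.12 ± 0.11 and -5.96 ± 0.09 to levels below the filter (-1.27 on another CLTRN probe set), and RIPPLY1, RANBP3L and PRR15 by -4.96 ± 0.20, -4.88 ± 0.13 and -4.73 ± 0.21.

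Proliferation genes rose with HGF. Of 22 measured mitosis genes 21 were higher and 0 lower, with a median change of 2.04 (21 adjusted over the list alone). KIF23, a kinesin of the central spindle, rose by 2.90 ± 0.09, PRC1, which bundles the same microtubules, by 3.02 ± 0.13, and cyclin A (CCNA2) by 2.65 ± 0.12. A second PRC1 probe set did not pass (0.09, adjusted p = 0.177). Of 25 genes of DNA replication and S phase 23 were higher and 1 lower (23 and 1 adjusted over the list alone), among them the clamp loader subunit RFC3 (2.05 ± 0.08) and the replication licensing inhibitor GMNN (1.24 ± 0.06). The camera adjusted p was 3.26e-10 for mitosis and 2.58e-07 for S phase. With an estimated correlation these became adjusted p = 0.115 and adjusted p = 0.1102. Of 9 cell cycle inhibitors 7 were also higher and 1 lower (7 and 1 adjusted over the list alone), with an adjusted p = 0.0362, and adjusted p = 0.101 with an estimated correlation. CDKN1A, the CDK inhibitor p21, rose by 5.72 ± 0.16 (4.83 and 1.502 on other probe sets) and CDKN2B by 3.78 ± 0.17 from below the filter, while RBL2, a pocket protein of quiescent cells, fell by 0.82 ± 0.06 (-0.44 on another probe set).

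Metabolic and stress-related lists moved up as well. Of 17 cholesterol synthesis genes 14 were higher and 0 lower (14 adjusted over the list alone), with a median change of 1.41 (adjusted p = 2.39e-07, and adjusted p = 0.0129 with an estimated correlation). CYP51A1, the sterol demethylase, rose by 2.02 ± 0.05, farnesyl diphosphate synthase FDPS by 2.60 ± 0.06 and the sterol feedback regulator INSIG1 by 2.88 ± 0.08. Of 20 glycolysis and hypoxia genes 18 were higher and 0 lower (18 adjusted over the list alone), with adjusted p = 8.33e-10, and adjusted p = 0.0851 with an estimated correlation. Its examples were phosphofructokinase PFKP (2.84 ± 0.08), hexokinase HK2 (2.70 ± 0.08, and 0.20 with adjusted p = 0.0349 on another probe set) and the glucose transporter SLC2A1 (2.64 ± 0.08). In the unfolded protein and ATF4 list 17 of 19 were higher and 2 lower (17 and 2 adjusted over the list alone), with adjusted p = 1.23e-05, and adjusted p = 0.0257 with an estimated correlation. ASNS, asparagine synthetase, rose by 2.19 ± 0.09 and the transcription factor ATF4 by 0.85 ± 0.04.

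Signalling and motility lists also rose. Of 13 ERK feedback and output genes 8 were higher and 0 lower (8 adjusted over the list alone, adjusted p = 0.000649, and adjusted p = 0.0851 with an estimated correlation). Cyclin D1 (CCND1) rose by 2.53 ± 0.07, the receptor EPHA2 by 2.34 ± 0.10 and the ERK phosphatase DUSP6 by 1.09 ± 0.06, while FOSL1, an AP-1 subunit, rose by 2.79 ± 0.52 from below the filter. Of 14 immediate early genes 10 were higher and 2 lower (10 and 2 adjusted over the list alone, adjusted p = 0.00575, and adjusted p = 0.115 with an estimated correlation). KLF6 rose by 2.67 ± 0.10 and KLF4 by 3.60 ± 0.16, while EGR1 fell by 1.31 ± 0.24. A second KLF4 probe set read 0.02 (adjusted p = 0.722). Of 18 genes of the actin cytoskeleton and SRF list 13 were higher and 0 lower (14 adjusted over the list alone, adjusted p = 4.03e-05, and adjusted p = 0.101 with an estimated correlation). CAPG, an actin filament capping protein, rose by 2.10 ± 0.06 and FHL2 by 1.61 ± 0.04. TPM4, a tropomyosin, rose by 1.60 ± 0.04 on its brightest probe set, by 1.11 to 2.35 on 4 others, and fell by 0.17 on another. Of 13 matrix proteases and inhibitors 8 were higher and 1 lower (8 and 1 adjusted over the list alone, adjusted p = 0.00165, and adjusted p = 0.0894 with an estimated correlation). Of 9 mesenchymal transition genes 5 were higher and 2 lower (5 and 2 adjusted over the list alone, adjusted p = 0.0288, and adjusted p = 0.101 with an estimated correlation). LOX, a collagen cross-linking enzyme, rose by 3.81 ± 0.12 from below the filter and S100A4 by 2.26 ± 0.09.

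The exocyst and ciliary transport list was the 1 list that moved down with HGF, with 4 of 27 higher and 13 lower (4 and 13 adjusted over the list alone, adjusted p = 0.0320, and adjusted p = 0.346 with an estimated correlation). The intraflagellar transport genes IFT57, IFT74 and IFT81 fell by 1.28 ± 0.05, 1.08 ± 0.05 and 2.38 ± 0.16 (-1.44 on another IFT81 probe set). The junction and polarity list went both ways, with 12 of 32 higher and 15 lower (12 and 15 adjusted over the list alone) and an adjusted p = 0.477. E-cadherin (CDH1) rose by 0.60 ± 0.09. The receptor MET rose by 0.78 ± 0.07 and the collagen-binding integrin ITGA2 by 0.84 ± 0.08. Members higher and lower were 2 and 8 of 18 for kidney tubule transport, 7 and 4 of 13 for integrins, 2 and 9 of 14 for HGF-Met signalling, 3 and 6 of 10 for NRF2 targets, 4 and 1 of 12 for apoptosis regulators, and 5 and 3 of 9 for EGF family members. They were 5 and 2 of 13 for nephron development, 3 and 1 of 11 for inflammatory mediators, 5 and 4 of 12 for p53 targets, 4 and 3 of 14 for basement membrane and matrix, 4 and 6 of 13 for the interferon response, and 2 and 3 of 7 for aryl hydrocarbon receptor targets. Neither these 12 lists nor the junction list passed, with adjusted p from 0.0819 to 0.979. Markers of other cell types were few, with 0 and 1 of 5 for fibroblasts, 0 and 0 of 5 for endothelium and 1 and 1 of 3 for leukocytes (adjusted p = 0.979 for each), and the leukocyte gene that rose was CD68 (3.03 ± 0.52), a lysosomal protein of macrophages.

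Over all 24904 probe sets, 13839 (55.6%) passed for HGF against Control, 6556 higher and 7283 lower, and 3467 of them changed by at least 1 on the log2 scale. Of the 12 lists that passed, 2 (cholesterol synthesis and the unfolded protein and ATF4 list) passed with an estimated correlation. The ratio of the 3' to the 5' control probe set of beta-actin moved with the HGF group, at 2.24 ± 0.05 in Control, 1.48 ± 0.08 in HGF, 2.13 ± 0.07 in HGF + PD and 2.15 ± 0.04 in HGF + UO (log2, SD). The HGF and Control arrays did not overlap, and the exact permutation p of 0.0286 is the smallest that 4 against 4 arrays allow (0.0762 adjusted over 24 array comparisons). The ratio of GAPDH, taken as the mean of 2 pairs of probe sets (2.03 and 0.228 in Control), was 1.13 ± 0.04 in Control and 1.06 ± 0.04 in HGF (exact permutation p = 0.0571). That of EF1a differed by -0.241 (exact permutation p = 0.143), with its 5' probe set near the filter level in all groups (4.06 to 4.22).

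**Figure D2:**
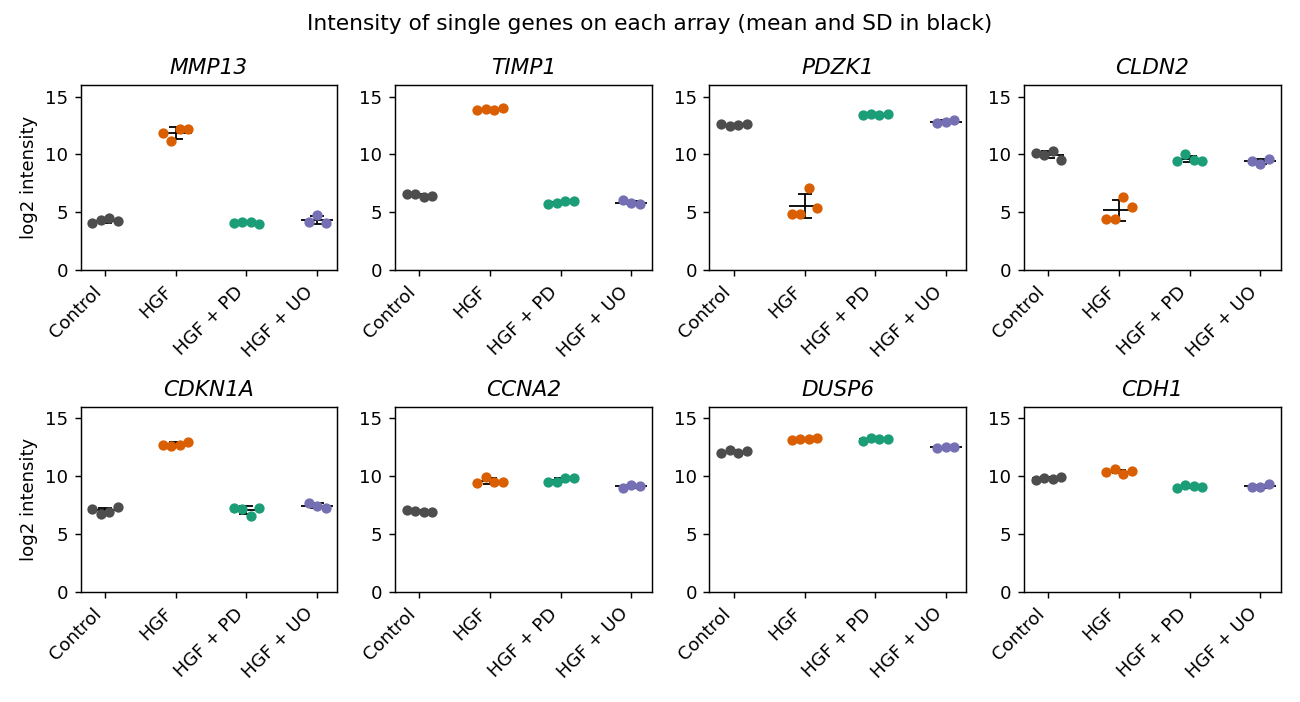
Log2 intensity of 8 genes on every array by group, with the mean and SD in black (n = 4, 4, 4 and 3). MMP13 rises from 4.27 to 11.85 with HGF and lies at 4.09 and 4.34 with PD and UO, while DUSP6 on the probe set shown stays near its HGF level with PD (13.20 against 13.22).

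PD at 50 uM, added with HGF, was compared with HGF alone to find which changes depend on the pathway it blocks. TIMP1 fell by 8.02 ± 0.09 (259.8-fold, adjusted p = 1.35e-16, n = 4 and 4) and MMP13 changed by -7.76 ± 0.20 (217-fold, adjusted p = 7.82e-13). MMP13 lay near the filter level with PD (4.09), so the size of its change depends on the GCRMA background. Changes were -5.67 ± 0.16 for CDKN1A (-4.92 and -1.52 on other probe sets), -5.96 ± 0.07 for S100A2, -5.53 ± 0.10 for the G protein regulator RGS2, -5.61 ± 0.14 for the ectonucleotidase ENTPD3 and -5.08 ± 0.16 for OLFM1. PDZK1 rose by 7.93 ± 0.35 (244-fold), SCG5 by 5.64 ± 0.26, CLDN2 by 4.43 ± 0.35 and DEPTOR, an inhibitor of mTOR, by 4.67 ± 0.20 (2.88 on another probe set). The glutathione transferase MGST1 and the membrane peptidase MME rose by 5.71 ± 0.23 and 5.19 ± 0.25 from below the filter. MET fell by 1.39 ± 0.07, ITGA2 by 2.00 ± 0.08 and CDH1 by 1.29 ± 0.09. DUSP6 differed by -0.01 ± 0.06 (adjusted p = 0.852, 95% interval -0.14 to 0.11), while a second DUSP6 probe set was lower (-0.24, adjusted p = 0.0263).

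Of the lists, 9 passed under PD against HGF and 5 of these also with an estimated correlation. Of 18 actin and SRF genes 15 were lower and 0 higher (15 adjusted over the list alone), with CAPG at -2.54 ± 0.06 (adjusted p = 8.69e-08, and adjusted p = 0.0383 with an estimated correlation). Of 14 immediate early genes 12 were lower and 1 higher (12 and 1 adjusted over the list alone, adjusted p = 4.44e-05), with FOS at -2.19 ± 0.07 and KLF6 at -3.07 ± 0.10. Matrix proteases (10 of 13 lower and 2 higher), cholesterol synthesis (13 of 17 lower and 0 higher) and the unfolded protein and ATF4 list (15 of 19 lower and 2 higher) moved down too, with the same counts adjusted over the list alone and adjusted p = 0.000138, 0.000124 and 0.000235. Each of these 5 lists had an adjusted p = 0.0383 with an estimated correlation. Glycolysis and hypoxia genes were lower in 18 of 20 (18 adjusted over the list alone, adjusted p = 1.25e-07, and adjusted p = 0.0782 with an estimated correlation). Integrins were lower in 8 of 13 and higher in 3 (8 and 3 adjusted over the list alone, adjusted p = 0.00339, and adjusted p = 0.0782 with an estimated correlation), among them the laminin receptor subunit ITGA6 (-4.14 ± 0.07). Its other probe sets read -4.20, -7.31 and -0.19, and the last did not pass (adjusted p = 0.1103). ERK output genes were lower in 6 of 13 and higher in 0 (6 adjusted over the list alone, adjusted p = 0.00595, and adjusted p = 0.105 with an estimated correlation), including CCND1 (-2.44 ± 0.07) and the phosphatase DUSP5 (-3.18 ± 0.18). Exocyst and ciliary genes were higher in 14 of 27 and lower in 3 (14 and 4 adjusted over the list alone, adjusted p = 0.0224, and adjusted p = 0.313 with an estimated correlation), with IFT57 at 1.72 ± 0.05. The mitosis list did not pass, with 6 of 22 higher and 6 lower (6 and 6 adjusted over the list alone, adjusted p = 0.811). In all 13798 probe sets passed, 7549 higher and 6249 lower. As many lists were called by 2 of the 35 splits of these 8 arrays, the real one included. The actin 3'/5' ratio rose back by 0.653 (exact permutation p = 0.0286, 0.0762 adjusted).

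UO at 10 uM, added with HGF, gave changes of -8.05 ± 0.10 for TIMP1 (266-fold, adjusted p = 3.04e-16, n = 3 and 4) and -7.51 ± 0.22 for MMP13 (182-fold). MMP13 lay near the filter level with UO too (4.34), with the same limit on its size. S100A2 fell by 6.42 ± 0.08, RGS2 by 5.85 ± 0.11, CDKN1A by 5.30 ± 0.17 (-4.87 and -1.62 on other probe sets), ENTPD3 by 5.55 ± 0.15 and OLFM1 by 5.20 ± 0.17. PDZK1 rose by 7.30 ± 0.38, SCG5 by 5.81 ± 0.28, CLDN2 by 4.24 ± 0.38, the metalloreductase STEAP2 by 4.72 ± 0.16 (2.15 and 1.85 on other probe sets) and DEPTOR by 4.57 ± 0.21 (2.69 on another probe set). MET read -1.41 ± 0.07, ITGA2 -2.18 ± 0.09, CDH1 -1.26 ± 0.09 and DUSP6 -0.74 ± 0.06 (adjusted p = 1.39e-07).

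Of the lists, 10 passed under UO against HGF and 6 of these also with an estimated correlation. Lower members were 16 of 18 for actin and SRF genes, 14 of 17 for cholesterol synthesis, 12 of 14 for immediate early genes, 10 of 13 for matrix proteases, 9 of 13 for ERK output and 13 of 19 for the unfolded protein and ATF4 list, with the same counts adjusted over the list alone. Higher members numbered 0, 0, 1, 1, 0 and 1, and the adjusted p of these 6 lists lay between 2.41e-07 and 0.000748, or between 0.0320 and 0.0470 with an estimated correlation. FOS read -2.99 ± 0.07, CCND1 -2.70 ± 0.08 and DUSP5 -4.18 ± 0.19. The sterol enzyme CYP51A1 fell by 1.72 ± 0.05. Glycolysis and hypoxia genes were lower in 18 of 20 (18 adjusted over the list alone, adjusted p = 1.59e-07, and adjusted p = 0.0733 with an estimated correlation). Integrins were lower in 8 of 13 and higher in 3 (8 and 3 adjusted over the list alone, adjusted p = 0.00559, and adjusted p = 0.0778 with an estimated correlation). NRF2 targets were higher in 7 of 10 and lower in 1 (7 and 1 adjusted over the list alone, adjusted p = 0.00711, and adjusted p = 0.116 with an estimated correlation), with the glutathione transferase GSTA4 at 1.69 ± 0.05. Mitosis genes were lower in 11 of 22 and higher in 0 (11 adjusted over the list alone, adjusted p = 0.0146, and adjusted p = 0.615 with an estimated correlation), with ANLN, a cytokinesis scaffold, at -2.66 ± 0.26 (-0.48 on another probe set) and KIF23 at -0.93 ± 0.10. In all 13060 probe sets passed, 6780 higher and 6280 lower. As many lists were called by 3 of the 35 splits of these 7 arrays, the real one included. The GAPDH 3'/5' ratio was higher with UO (1.25 ± 0.02, SD) than on the HGF arrays without overlap (exact permutation p = 0.0286, 0.0762 adjusted), and the actin ratio was higher by 0.669 (exact permutation p = 0.0286, 0.0762 adjusted), while the EF1a ratio differed by 0.114 (exact permutation p = 0.543).

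Most HGF changes were opposed by either inhibitor. PD at 50 uM opposed 10355 of the 13839 HGF calls (74.8%), UO at 10 uM 10749 (77.7%), and 9698 (70.1%) were opposed by both. Among the 3467 HGF calls of at least 1 on the log2 scale, 3118 (89.9%) were opposed by both. Neither inhibitor opposed 2433 (17.6%). An opposed call need not be a full return to Control. Under PD, 36.8% of the HGF calls higher and 24.1% of those lower were still called the same way against Control. Under UO these were 23.3% and 17.9%. Opposition could also pass the Control level, as for ITGA2 (-1.16 and -1.35 against Control under PD and UO). Independent sets of calls would overlap in 1645 (HGF up, PD down) and 2208 (HGF down, PD up), where 4769 and 5586 were seen. For UO these were 1653 and 1983 against 5169 and 5580. Simulated unchanged groups that shared the HGF arrays gave at most 2 opposed probe sets in 20 simulations. No HGF change was simulated, so HGF calls were hardly expected there. This count therefore does not show what the shared arrays add among the real HGF calls. With the HGF arrays split, the median share of the HGF change that was opposed was 83.3% for PD (79.7% to 87.5% over 6 splits) and 86.6% for UO (82.5% to 90.9%). Across probe sets, which are not independent replicates, the PD and UO changes against HGF had a Pearson r of 0.964, and 0.940 (0.929 to 0.947) with separate HGF arrays. The simulated r averaged 0.410, and the covariance was 0.641 against a simulated 0.00611. Genes opposed by both included MMP13, TIMP1, SNAI2 and PTGS2 among those raised and PDZK1, NTN4 and CLDN2 among those lowered.

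**Figure D3:**
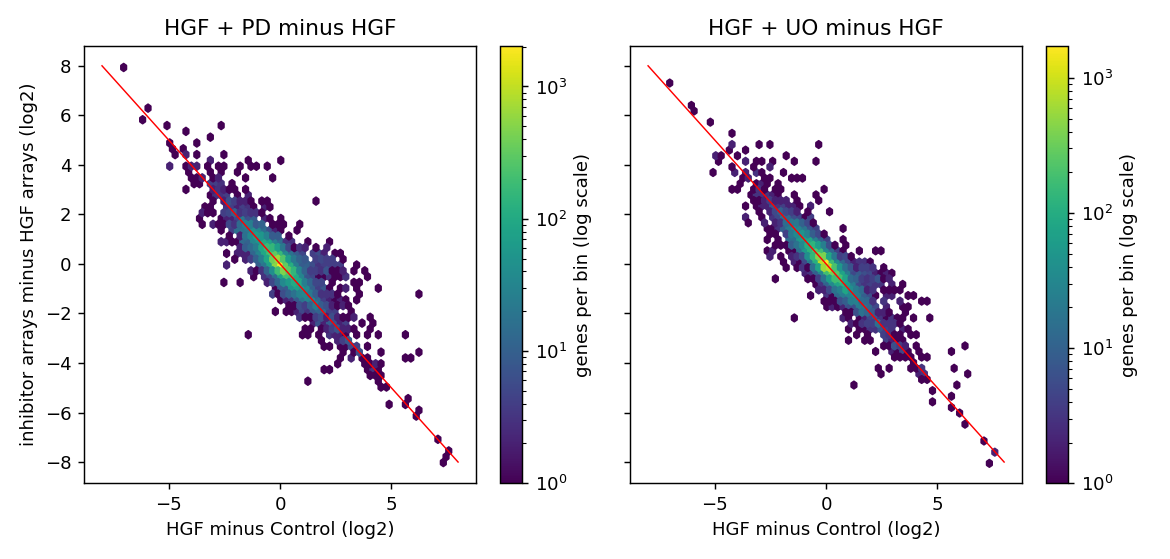
Log2 change of each of 10286 genes with HGF against Control (x) and with inhibitor and HGF against HGF alone (y), PD on the left and UO on the right, colour giving genes per bin on a log scale and the red line full opposition. Genes tend to lie along the line in both panels, but not all do. Over all probe sets, neither inhibitor opposed 17.6% of the HGF calls. Both axes share the HGF arrays.

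UO at 10 uM and PD at 50 uM were then compared directly. DKK3, a secreted glycoprotein of the Dickkopf family, was lower with UO by -3.49 ± 0.20 (95% interval -3.92 to -3.05, adjusted p = 7.52e-07, n = 3 and 4), although a second DKK3 probe set read -0.03 (adjusted p = 0.902). HEPH, a ferroxidase, read -1.94 ± 0.13, FGFBP1, a carrier of fibroblast growth factors, -2.12 ± 0.31, GPR18 -2.03 ± 0.37 and SYT13 -1.62 ± 0.26. Higher with UO were TGFB2 (1.39 ± 0.31), FILIP1L (1.34 ± 0.32), HABP2 (1.29 ± 0.20), the inositol transporter SLC5A3 (1.16 ± 0.24) and IL13RA2 (1.15 ± 0.23). HABP2 with PD and GPR18 with UO lay below the filter (3.48 and 3.80), so that the size depends on the GCRMA background. A second TGFB2 probe set read 0.40 and did not pass (adjusted p = 0.0974). Of 3 other FILIP1L probe sets 2 passed (0.92 and 1.46) and 1 did not (0.22). In a fit of these groups alone TGFB2, SLC5A3 and GPR18 did not pass, nor did TGFB2 without HGF + UO array 2 or FILIP1L without HGF + PD array 3 or HGF + UO array 1 or 2. DUSP6 was lower with UO by -0.72 ± 0.06 (adjusted p = 2.54e-05). Differences of MMP13 (0.25, 95% interval -0.22 to 0.73), TIMP1 (-0.03, -0.24 to 0.18), MET (-0.02, -0.17 to 0.14), CDH1 (0.04, -0.16 to 0.24) and CLDN2 (-0.20, -1.01 to 0.61) did not pass.

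Cell cycle lists were lower with UO than with PD. Lower members were 10 of 22 for mitosis (15 adjusted over the list alone, adjusted p = 2.39e-06, and adjusted p = 0.476 with an estimated correlation) and 11 of 25 for S phase (15 adjusted over the list alone, adjusted p = 5.14e-06, and adjusted p = 0.274 with an estimated correlation). For cholesterol synthesis they were 7 of 17 (8 adjusted over the list alone, adjusted p = 1.97e-05, and adjusted p = 0.0429 with an estimated correlation). NRF2 targets (3 of 10 higher, 0 lower), basement membrane and matrix (3 of 14 higher, 1 lower) and junctions (2 of 32 higher, 1 lower) moved up, with adjusted p = 0.00821, 0.0196 and 0.0371. With an estimated correlation these became adjusted p = 0.264, adjusted p = 0.264 and adjusted p = 0.600, and adjusted over the list alone 5 and 1, 5 and 1, and 2 and 2 members passed. In all 2295 probe sets passed, 636 higher (27.7%) and 1659 lower, and 72 of them changed by at least 1 on the log2 scale. The share higher was 41.4% after quantile and 38.0% after cyclic loess normalisation, a fit of these groups alone called 997 probe sets, array weights gave 4340, and leaving out HGF + PD array 4, HGF + UO array 1, 2 or 3 gave 1207, 1481, 1252 and 1472. As many lists were called by 9 of the 35 splits of these 7 arrays, the real one included, and the GAPDH 3'/5' ratio was higher with UO than with PD by 0.166 (exact permutation p = 0.0286, 0.0762 adjusted over 24). The EF1a ratio went the other way (-0.143, with the same exact and adjusted p).

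The inhibitor groups were then compared with Control, which received medium alone. Such differences mix what was left of the HGF response with any effect of the compound or its vehicle. Without arrays of cells given a compound alone, these cannot be told apart. Mitosis genes remained above Control in 21 of 22 under PD at 50 uM (median 2.06, 21 adjusted over the list alone, adjusted p = 2.33e-17) and in 20 of 22 under UO at 10 uM (median 1.57, 21 adjusted over the list alone, adjusted p = 3.88e-20), and 0 were lower. With an estimated correlation these became adjusted p = 0.123 and adjusted p = 0.0813. KIF23 was above Control by 2.39 ± 0.09 under PD and 1.97 ± 0.10 under UO, and CCNA2 by 2.72 ± 0.12 and 2.18 ± 0.13. S phase genes were higher in 22 of 25 and lower in 0 under PD (23 adjusted over the list alone, adjusted p = 5.86e-15, and adjusted p = 0.0644 with an estimated correlation). Under UO 19 were higher and 1 lower (23 and 1 adjusted over the list alone, adjusted p = 5.88e-15, and adjusted p = 0.0644 with an estimated correlation). Cholesterol synthesis genes were higher in 12 of 17 under PD and 10 under UO and lower in 0 (12 and 11 adjusted over the list alone), with adjusted p = 1.36e-07 and 3.36e-06, or adjusted p = 0.0121 and adjusted p = 0.0279 with an estimated correlation. SNAI2 stayed above Control by 1.92 ± 0.18 under PD and 0.83 ± 0.19 under UO, PTGS2 by 2.70 ± 0.21 and 1.85 ± 0.23, and DUSP6 by 1.07 ± 0.06 and 0.35 ± 0.06. The SNAI2 difference under UO did not pass in a fit of only these groups. MMP13 differed from Control by -0.18 ± 0.20 under PD and 0.07 ± 0.22 under UO (adjusted p = 0.533 and 0.883).

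Junction genes lay below Control under both inhibitors, with 23 of 32 lower and 1 higher under PD (24 and 1 adjusted over the list alone, adjusted p = 7.07e-09, and adjusted p = 0.133 with an estimated correlation). Under UO 18 were lower and 0 higher (21 and 1 adjusted over the list alone, adjusted p = 9.27e-08, and adjusted p = 0.162 with an estimated correlation). CDH1 fell by 0.69 ± 0.09 and 0.66 ± 0.09 under PD and UO, and MET by 0.61 ± 0.07 and 0.63 ± 0.07. Interferon response genes were lower in 8 of 13 and higher in 0 under either compound (8 and 10 lower adjusted over the list alone, adjusted p = 0.000142 and 2.45e-05), with adjusted p = 0.133 and adjusted p = 0.118 with an estimated correlation. Among 14 immediate early genes 8 were lower and 2 higher under PD, and 7 and 2 under UO (the same counts adjusted over the list alone), with EGR1 at -4.10 ± 0.24 and -3.45 ± 0.26. Their adjusted p was 0.00477 and 0.00233, and adjusted p = 0.134 and adjusted p = 0.162 with an estimated correlation. In all 8579 probe sets passed under PD (5028 higher, 3551 lower) and 5550 under UO (2976 higher, 2574 lower). The share higher under PD, 58.6%, was 51.1% after quantile and 55.5% after cyclic loess normalisation, and under UO 53.6%, 51.9% and 53.6%. Both groups were higher for 2539 probe sets and lower for 1776, where independent sets of calls would share 600.84 and 367.02, and part of this excess may come from the shared Control arrays. Of the lists, 12 passed under PD and 11 under UO, 1 in each with an estimated correlation, and 2 of the 35 splits of the PD and Control arrays, the real one included, called as many lists. The GAPDH 3'/5' ratio was higher with UO than in Control by 0.116 (exact permutation p = 0.0286, 0.0762 adjusted), while the EF1a ratio differed by -0.127 and the hybridisation controls by -0.298 on the log2 scale (the same exact and adjusted p for each).

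**Figure D4:**
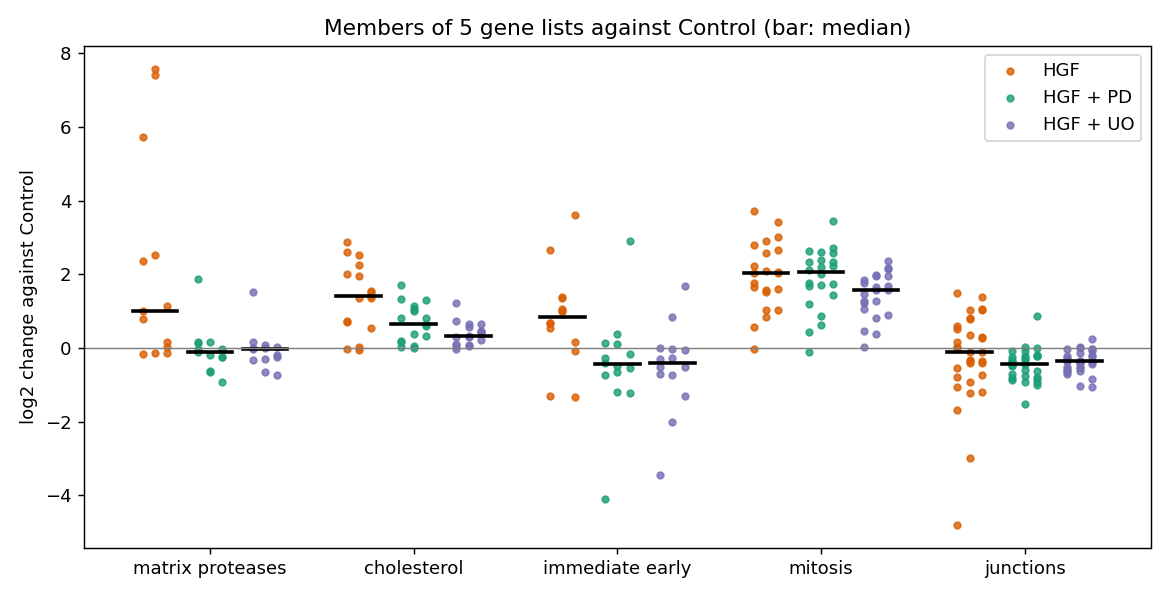
Log2 change against Control of the members of 5 gene lists in the HGF, HGF + PD and HGF + UO groups, each point 1 gene and each black bar the median. The mitosis list has medians of 2.04, 2.06 and 1.57, and the junction list lies below 0 under both inhibitors with medians of -0.42 and -0.36.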

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

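The tests of array scaling were chosen after the result was seen, as was the use of the actin ratio beside that of GAPDH. Arrays were marked when the gap between the highest or lowest array of a group and its nearest neighbour, divided by the range of the group, exceeded the critical value for 4 arrays. Of 303 groups tested 29 (9.57%) exceeded it, where chance gives about 1 in 20.

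The HGF arrays stood apart from the other groups on the first component, in 1 direction for all 4 arrays. A shift in array scaling of 1 or more on the log2 scale, left after the GCRMA normalisation, is argued against by the bacterial hybridisation controls. These differed by -0.103 between HGF and Control on the log2 scale (exact permutation p = 0.457). The controls had an SD of 0.236 across the HGF arrays, so they cannot exclude a smaller shift. They were read after that normalisation and do not bear on a shift that it removed. For RNA degradation, the bound set beforehand on the GAPDH 3'/5' ratio was met (HGF minus Control -0.0706, exact permutation p = 0.0571). That bound rested on 1 transcript and was too narrow, because the actin ratio differed by -0.758 with no overlap, while actin itself rose by 0.81 at its 3' and by 1.57 at its 5' control probe set, and the EF1a ratio (-0.241, exact permutation p = 0.143) decides little with its 5' probe set near the filter level. Unequal RNA quality and regulation or signal limits of actin therefore cannot be told apart here, and the response to HGF, which the design names, stays open beside them. The mean GAPDH, actin and EF1a ratios were all lower on the HGF arrays, whereas degradation raises such a ratio. None of them points to more degraded RNA in the HGF group. The GAPDH ratio did not follow the first component. It was 1.06 in HGF and 1.08 in HGF + PD, which lay at 92.3 and -32.5 there. It was highest in HGF + UO (1.25), which lay at -34.3, beside Control at -34.1. Unequal RNA quality as read by GAPDH is therefore argued against as the source of that component, while the actin ratio did move with it.

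Other groupings of the same arrays tested whether chance could give the counts. The real grouping alone, 1 of 35, gave as many probe sets in each of the 6 comparisons. The real counts were 13839 for HGF against Control (highest other 1), 13798 for PD against HGF (highest other 0), 13060 for UO against HGF (8643), 2295 for UO against PD (1734), 8579 for PD against Control (4) and 5550 for UO against Control (1851). The high other counts with UO came from a structure of the samples, since such splits set 3 arrays of the larger group against the UO arrays and 1 more. For opposed probe sets the real grouping alone, 1 of 100, reached 10355 for PD (highest other 0), 10749 for UO (highest other 1) and 9698 for both (highest other 0). The number of lists called exceeded all other splits for HGF against Control (12, highest other 10, 1 of 35) and UO against Control (11, highest other 9, 1 of 35). These splits cannot exclude chance for the number of lists in PD against HGF (9, highest other 10, 2 of 35), UO against HGF (10, highest other 10, 3 of 35), UO against PD (6, highest other 10, 9 of 35) and PD against Control (12, highest other 12, 2 of 35). Except in UO against PD, every other split that reached as many lists kept 3 arrays of 1 group on the same side. Such splits keep part of the real difference, so they are no clean measure of chance.

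On HGF array 2 the gap made up 0.854 of the range for DSG3, 0.907 for SNAI2, 0.962 for RFC3, 0.870 for GMNN, 0.858 for CCNA2 and 0.871 for CDKN2B, with RFC3 at 10.44 against 10.15 to 10.16 on the others. On HGF array 3 it was 0.886 for CLTRN, 0.992 for MME and 0.880 for the first component (87.8 against 93.5 to 94.3). It was 0.881 for TEX26 on HGF array 1 and 0.882 for 1 GAPDH 3'/5' ratio on HGF array 4. On Control array 1 it was 0.844 for SNAI2, 0.853 for TEX26, 0.894 for PRR15, 0.941 for CDKN2B and 0.959 for DKK3. On Control array 3 it was 0.958 for PTGS2 and 0.920 for RFC3. On HGF + PD array 1 it was 0.955 for ITGB3 and 0.830 for HEPH, and on array 2 it was 0.833 for NTN4, 0.843 for CLDN2, 0.915 for NDRG1 and 0.848 for SYT13. On HGF + PD array 3 it was 0.870 for CDKN1A and 0.838 for SLC2A1, and on array 4 it was 0.912 for MET, 0.953 for ANLN and 0.879 for the percent of probe sets at the filter level (56.91 against 56.98).

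The effect of adding an inhibitor to HGF differed between UO and PD by limma's test of the difference for 11 named genes. UO minus PD was 1.39 for TGFB2, 1.34 for FILIP1L, 1.29 for HABP2, 1.16 for SLC5A3 and 1.15 for IL13RA2. It was -3.49 for DKK3, -2.12 for FGFBP1, -2.03 for GPR18, -1.94 for HEPH, -1.62 for SYT13 and -0.72 for DUSP6, at 10 uM against 50 uM. All but DUSP6 were named for the size of this same difference, so the test repeats their selection. The limits given above for DKK3, TGFB2, FILIP1L, SLC5A3, GPR18 and HABP2 apply here too.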

How the results depend on the processing

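All alternatives reported here were fixed before the data were examined. Requiring a change of at least 1 on the log2 scale left 3467, 3385, 3380, 72, 820 and 574 probe sets for HGF against Control, PD against HGF, UO against HGF, UO against PD, PD against Control and UO against Control, fewer by construction. It left 2455 probe sets opposed by PD, 2571 by UO and 2321 by both, with an opposed share of 87.3% for PD and a correlation of 0.983. The count for UO against PD (2295) was the 1 that moved by over 1.5 times elsewhere, to 997 in a fit of only these groups and 4340 with array weights, and from 1207 (without HGF + PD array 4) to 2923 (without HGF + PD array 2) when 1 array was left out. Without HGF + UO array 1, 2 or 3 it was 1481, 1252 and 1472, and the cause was not tested. The lists called fell to 2, 5, 6, 1, 1 and 1 with an estimated correlation, in the order of comparisons above, because that test allows for correlated members. TPM4 changed direction on 1 of its 5 other probe sets in HGF against Control (-0.17), PD against HGF (0.0278) and UO against HGF (0.0529), as did ITGB1 in UO against HGF (0.0374), and the cause was not tested. Of these only the TPM4 value in HGF against Control passed (adjusted p = 0.0337). Of 233 pairs of a named gene and a comparison, 220 kept their call under all alternatives on the same probe set and 206 on other probe sets too. Of 168 pairs of a list and a comparison 0 changed direction and 56 changed their call under at least 1 alternative.

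Replicate numbers did not pair the arrays. Deviations from the group means correlated over 0.1 in 8 of 21 pairs of arrays with the same number (range -0.247 to 0.412), and 5 of 15 arrays matched best with their own number. With the number as a block, 13924, 13850, 12919, 1858, 8820 and 5550 probe sets passed in the order above, and 10417, 10706 and 9744 were opposed by PD, UO and both. The block ended 1 call of a named gene, RANBP3L in UO against Control, and no call of a list.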

Other observations

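The tests of the mitosis genes and of NQO1 and CYP1B1 were chosen after the result was seen, and the single genes named here outside the rule were chosen after their values were seen. TGFBI, a secreted matrix protein, fell with HGF by 1.39 ± 0.15 and lay above Control by 2.91 ± 0.15 under PD and 2.77 ± 0.16 under UO (adjusted p = 5.26e-09 and 4.32e-08, limma). The claudin CLDN4 rose with HGF by 1.04 ± 0.07 and fell below Control by 1.00 ± 0.07 and 1.07 ± 0.08. STAT3 fell below Control by 1.06 ± 0.07 under PD and 0.74 ± 0.07 under UO. The organic cation transporter SLC22A2 fell by 3.63 ± 0.10 with HGF and was still below Control by -1.85 ± 0.10 and -1.82 ± 0.10 with the inhibitors. The interferon-induced OAS2 rose with HGF by 1.65 ± 0.10 and read -0.80 ± 0.10 and -0.71 ± 0.11 against Control under PD and UO.

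Further lists differed from Control under the inhibitors. Kidney tubule transport genes were lower in 6 of 18 and higher in 1 under PD (adjusted p = 0.0166, and adjusted p = 0.140 with an estimated correlation), and lower in 5 and higher in 0 under UO (adjusted p = 0.0177, and adjusted p = 0.162 with an estimated correlation). HGF-Met signalling genes were lower in 7 of 14 and higher in 2 under PD and lower in 6 and higher in 0 under UO (adjusted p = 0.00349 and 0.00621), with adjusted p = 0.262 and adjusted p = 0.310 with an estimated correlation. Actin and SRF genes were lower in 11 of 18 and higher in 1 under PD and lower in 6 and higher in 1 under UO (adjusted p = 0.000111 and 0.00238), with adjusted p = 0.133 and adjusted p = 0.208 with an estimated correlation. Integrins were lower in 5 of 13 and higher in 2 under PD and lower in 4 and higher in 0 under UO (adjusted p = 0.0166 and 0.0184), with adjusted p = 0.134 and adjusted p = 0.162 with an estimated correlation. Glycolysis genes stayed higher in 13 of 20 and 11 of 20 and lower in 1 (adjusted p = 0.000241 and 1.69e-05), with adjusted p = 0.194 and adjusted p = 0.162 with an estimated correlation. Basement membrane genes were lower in 6 of 14 and higher in 0 under PD (adjusted p = 0.00477, and adjusted p = 0.133 with an estimated correlation).

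Mitosis genes stayed above Control under both inhibitors while most HGF changes were opposed, although the list did not pass with an estimated correlation (adjusted p = 0.123 for PD and adjusted p = 0.0813 for UO). The S phase list, also of proliferation genes, went the same way. Its opposed share over splits of the HGF arrays was -9.70% for PD and 19.5% for UO, beside 5.19% and 27.0% for mitosis. A block equally incomplete for all genes would give equal opposed shares. Those of the ERK output and immediate early lists were at least 51.4 percentage points above that of the mitosis list in every split of the HGF arrays. Of members raised by HGF in these lists, in that order, PD opposed 6 of 8, 10 of 10 and 6 of 21. UO opposed 7 of 8, 10 of 10 and 11 of 21. Their median shares were 87.1%, 127.8% and -0.364% for PD and 84.4%, 123.1% and 18.9% for UO. The mitosis list was picked for staying above Control, which is itself a low opposed share, so the gap restates the pattern. It is no separate support against an equal block. Single members overlapped, from 1.28% for DUSP6 under PD to 68.0% for the highest mitosis gene, and a partial block to which genes differ in sensitivity stays open. A single Control array as the cause is argued against by at least 19 of 22 mitosis genes above Control when 1 was left out, while a chance pick of this list stays open, because its percentile of 100 among random lists matched on the HGF change scores the difference that drew attention to it and does not allow for correlation between members. A part of the proliferative response that does not need the blocked pathway may account for it, which was not tested, and arrays of cells given each compound without HGF, with ERK phosphorylation measured beside them, would test it.

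CYP1B1 lay above Control by 1.83 ± 0.10 under PD and 2.17 ± 0.11 under UO, NQO1 by 2.63 ± 0.10 and 2.97 ± 0.11, and TIPARP by 2.03 ± 0.06 and 2.15 ± 0.06, where HGF alone moved them by -0.44, 2.44 and 0.71. Activation of the aryl hydrocarbon receptor (AhR) by the compounds may raise such genes, and 2 of its 7 measured targets (CYP1B1 and TIPARP) were above both Control and HGF under both inhibitors. For NRF2 activation these were 2 of 10 (GSTA4 and FTH1), and against random lists matched on the HGF change the AhR list lay at percentiles 99.99 and 100 and the NRF2 list at 72.58 and 96.92 for PD and UO, lists that hold the genes of the pattern themselves. The criterion for arguing against either explanation, a share of members under 25%, was widened to require also that the list as a whole did not rise in these comparisons after the counts had been seen, and without that addition NRF2 would have been argued against. NRF2 targets rose as a list under UO against HGF (adjusted p = 0.00711, and adjusted p = 0.116 with an estimated correlation) but not under PD against HGF (0.0666) or against Control (0.780 and 0.106), and AhR targets passed in none of these comparisons (0.0971 to 0.347), so the 2 explanations cannot be told apart, and a compound effect without HGF was not tested.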
